A study of Homo sapiens with 12 samples.

How the data were processed

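RNA was sequenced from MCF10A cells, a non-tumorigenic human breast epithelial cell line. Derivatives of the line stably carried 1 of 3 constructs: an empty vector, a wild-type TIP60 construct that the siRNA does not target, or a resistant construct whose product lacks catalytic activity. TIP60 is a lysine acetyltransferase encoded by KAT5. Each derivative received control siRNA or TIP60 siRNA and was harvested 72 h after transfection, which gave 6 groups of 2 libraries and 12 libraries in all. RNA was extracted with TRIzol and libraries were made with a stranded mRNA kit.

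Per the submitters' processing notes, reads were aligned with STAR to hg38 (GRCh38); the versions are not given in the sources used here. The deposited value is a fraction: per the file headers, it is the MISO posterior mean of the inclusion level, the share from 0 to 1 of an event's transcripts that carry the cassette exon. It is rounded to 2 decimals, comes with the bounds of an interval taken as 95%, and is a share within the event, so that it is not scaled to library size. Every event has 2 isoforms, with and without the exon. The deposited tables also give raw numbers of reads that fit only the form with the exon, only the form without it, both forms, or neither. Reads fitting only 1 form are called isoform-specific here.

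Events were placed on genes and exon classes with GENCODE release 29. Of 8380 events on primary chromosomes, 8379 overlapped a gene and 8370 had their cassette exon annotated. For 133 events more than 1 gene matched equally well. The tables listed 8712 events in any library and 4992 in all 12. An event was tested when it had at least 10 isoform-specific reads in each of the 12 libraries, which left 2695 events in 1887 genes. Of these, 169 lie on alternate or unplaced contigs, and a fit on primary chromosomes alone was run as an alternative.

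The inclusion level was compared with limma 3.58.1 in R 4.3.3. One factor of 6 groups was fitted to all 12 libraries, with an empirical Bayes variance trend on the mean log2 isoform-specific reads and the robust option. The p-values are two-sided and were adjusted by the Benjamini-Hochberg method over all events of a comparison, with a threshold of 0.05. The 9 comparisons were TIP60 siRNA against control siRNA within each construct, the 3 differences between those siRNA effects, either resistant construct against empty vector under control siRNA, and the resistant constructs against each other under TIP60 siRNA. A set shift was measured on the events with an unadjusted p under 0.01 in empty-vector cells: the mean siRNA effect in another line, signed by the direction in empty-vector cells, was tested with the directional p of limma's fry, adjusted over the 3 shifts of a fit; this asks whether the set moves on balance 1 way and does not compare it with other events. The p-value that picked the events and fry took their spread from the same libraries, so that the p-values of fry can be too small. Only the fits on the libraries of each comparison kept picking and test apart. Separated events were counted within each construct as those whose TIP60-siRNA libraries all lay at least 0.1 above, or all at least 0.1 below, the control-siRNA libraries. The same count for the other 2 ways to split the 4 libraries served as background, since 2 libraries against 2 allow no exact p below 0.333.

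Fixed gene lists, 14 in number, covered the NuA4/TIP60 complex, SR proteins, hnRNPs and other splicing regulators, the epithelial-mesenchymal splicing programme, DNA damage response, apoptosis, chromatin factors, cell cycle, actin and adhesion, RNA decay, the interferon response, and markers of epithelial, mesenchymal and immune cells. A list was tested with Fisher's exact test, two-sided, on the number of its genes with an event at an unadjusted p under 0.01, against all other genes with a tested event, adjusted over lists and the 3 siRNA comparisons. No immune marker had a tested event. As a proxy of expression, the reads of an event that fit at least 1 isoform were expressed per 1000000 such reads of the library (RPM), 0.5 was added, and log2 values were compared with limma over the 4992 events. Event reads are not a gene count, since they cover the exons of an event alone.

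The groups, comparisons, main tests, gene lists, rule for named genes and most alternatives were set before the data were examined. The rule named, for each siRNA comparison, every tested KAT5 event, up to 10 largest rises and 10 largest falls past the threshold with non-overlapping libraries, filled to 10 by the smallest p where fewer passed, and the 2 members of smallest p of each list. For the other comparisons it named the 5 events of smallest p. A few exons that the rule named are not reported singly here and remain in the counts of events and lists. The average siRNA effect over the 3 lines, event sets picked in the other lines, set shifts of event reads, read-based models with a replicate term, separated events and gene lists without each library, and primary chromosomes alone were added after the values had been seen.

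The replicate numbers pair the libraries. After removal of group means, deviations of libraries with the same number correlated between groups with Pearson r from 0.706 to 0.779 in all 15 pairs of groups, across events that are not independent replicates. A fit with the replicate number as a term, called the replicate block, was therefore run beside every comparison. Other alternatives were at least 20 reads, no read minimum, log2 odds of the level (offset 0.01), the log2 ratio of isoform-specific reads, a quasi-binomial model of those reads, weights from the intervals (widths below 0.05 set to 0.05), plain empirical Bayes, only the libraries of a comparison, a change of at least 0.1, event sets at p under 0.001 or 0.05, gaps of 0.2 and 0.05, a pseudocount of 5, scaling by the median of ratios, and leaving out each library. Where leaving out a library left 1 in its group, limma's pooled spread was assumed for it.

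The procedure was tested on simulated data that kept the read numbers of the 2695 events, with 100 events changed by 1 and 100 by 2 units of log odds. The group-only limma fit called 1% and 3% of these in the empty-vector comparison, with 2 unchanged events called. The replicate block called 1% and 9%, with 4 unchanged events called. The direction was right for 81% and 86% in both. In a line simulated without a response, the set shift was 0.0108 over 38 events and fry did not call it. Set shifts were not simulated in 2 lines with equal responses, so that the test of a difference between responding lines was not checked.

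Parsing, list tests and plots used Python 3.11.15, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. All p-values measure the spread between these libraries only, because the labels do not say whether libraries of a group came from separate cultures. Intervals of read numbers cover counting error only, and 0 reads allow up to 3 counts. Raw reads, events of other types than exon skipping, and gene-level expression were not analysed here.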

Results

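The data were exon inclusion levels from 12 RNA-seq libraries of MCF10A breast epithelial cells, with 2 libraries in each of 6 groups formed by 3 constructs and 2 siRNAs. The libraries numbered 1 held from 1983221 to 2280488 reads that fitted an isoform of an event, and 6921 to 7939 events each. The libraries numbered 2 held from 1277953 to 1566296 such reads and 6036 to 6599 events. The median event had 21 to 27 isoform-specific reads and a 95% interval 0.26 to 0.3 wide in the first set, against 13 to 17 reads and a width of 0.37 to 0.43 in the second. Reads that fitted neither isoform made up 50.1% to 53.2% of all event reads in the first set and 64.5% to 65.7% in the second. Both sets held all 6 groups. Across events, Pearson r between libraries was 0.953 to 0.985 within a set and 0.89 to 0.93 between sets, and the set means of 613 of 2695 events (22.7%) differed by over 0.1.

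KAT5, the gene of TIP60, had 1 listed event, a coding exon of 156 nt on the plus strand of chromosome 11 from 65713348 to 65713503 (ENSG00000172977.12, hg38). The first question was whether the siRNA lowered KAT5 and whether the constructs were present. Reads of the form with the exon fell with TIP60 siRNA from 9.73 ± 4.71 to 2.01 ± 1.36 RPM (SD, n = 6 libraries each; RPM counts reads of the event per 1000000 event reads of the library), a ratio of 0.207, and were lower in 6 of 6 same-number pairs (exact paired permutation, two-sided p = 0.0313, the smallest that 6 pairs allow). In empty-vector cells they were 17.2 and 5.84 RPM with control siRNA and 2.52 and 1.52 with TIP60 siRNA. In wild-type TIP60 cells the values were 11.6 and 5.31 against 2.74 and 1.34. In catalytically dead TIP60 cells they were 12.02 and 6.38 against 3.95 and 0, where 0 of the library's reads allows up to 3 counts. These values rest on 37 and 8 reads in the control libraries of empty-vector cells and on 5 and 2 reads in their TIP60-siRNA libraries.

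The form of KAT5 without the exon marked the lines with a construct. In RPM it stood at 8.38 and 0.731 in empty-vector control libraries, 2291 and 93.0 in wild-type control libraries and 987.7 and 35.1 in catalytically dead control libraries. With TIP60 siRNA they were 2.52 and 0, 1654 and 76.8, and 885.3 and 28.2 in the same order of lines. Under TIP60 siRNA the catalytically dead line had 0.535 times the wild-type value in the first set and 0.367 times in the second. KAT5 inclusion was 0.02 or lower in all 8 libraries with a construct, against 0.28, 0.5, 0.2 and 0.69 in the empty-vector libraries, and the event missed the read minimum for the test of levels. Total KAT5 event reads differed with TIP60 siRNA by −1.97 on the log2 scale in empty-vector cells (SE 2.37, limma adjusted p = 1.00), by −0.39 in wild-type cells and by −0.36 in catalytically dead cells, with limma p-values that did not pass and that did not pass with the replicate block either (adjusted p = 0.225 in empty-vector cells). Without a replicate term, leaving out 1 library sets unequal shares of the 2 replicate sets against each other, and the direction in wild-type cells turned to 1.93 without control replicate 1 and 1.87 without TIP60-siRNA replicate 2 of that line. In catalytically dead cells it turned to 1.97 without control replicate 1 and 2.16 without TIP60-siRNA replicate 2. Within same-number pairs the form without the exon was lower with TIP60 siRNA each time, with ratios of TIP60-siRNA to control RPM of 0.722 and 0.826 in wild-type cells and 0.896 and 0.802 in catalytically dead cells.

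**Figure D1:**
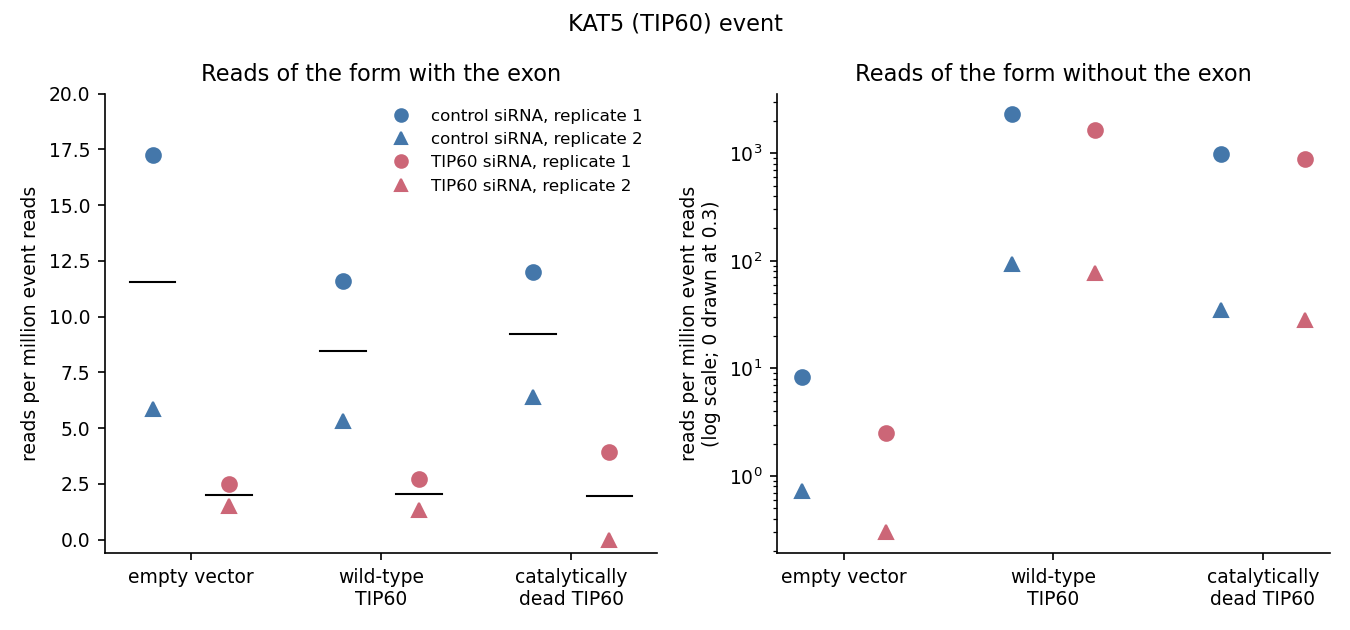
Reads of the KAT5 event in RPM of each library, for the form with the exon (left, linear axis, black lines are means of 2 libraries) and the form without it (right, log axis, 0 drawn at 0.3). The form with the exon was lower with TIP60 siRNA in 6 of 6 pairs, and the form without it was highest in the wild-type line, at 2291 RPM.

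The siRNA comparison in empty-vector cells asked how depletion of TIP60 affected exon choice where no resistant copy was present. A 27-nt coding exon of MARK3, which encodes a microtubule affinity-regulating kinase, fell from an inclusion level of 0.385 ± 0.0354 (SD, n = 2) to 0.02 in both TIP60-siRNA libraries. It lies on chromosome 14 from 103498502 to 103498528 and changed by −0.365 (SE 0.0342, limma adjusted p = 0.0365). The largest of the other named differences did not pass the correction. A coding exon of MYL6, an essential light chain of myosin (chromosome 12, 56160626 to 56160670), had levels of 0.745 ± 0.163 with control and 0.24 ± 0.0283 with TIP60 siRNA (SD, n = 2). ADD3, an adducin that caps actin filaments at the spectrin network, had 0.19 ± 0.0424 and 0.65 ± 0.099 at chromosome 10, 110132305 to 110132400.

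Other exons with non-overlapping libraries in empty-vector cells and lower levels were in SLC37A2, a sugar-phosphate transporter (−0.47 ± 0.0742, difference ± SE), AMIGO2, an adhesion molecule (−0.21 ± 0.0366), DIAPH1, a formin (−0.195 ± 0.0273), AKT2, a kinase of insulin signalling (−0.105 ± 0.016), the 5' UTR of HNRNPC, a pre-mRNA binding protein (−0.09 ± 0.0161), and CDIPT, a phosphatidylinositol synthase (−0.055 ± 0.00818). PPP3CB, a catalytic subunit of calcineurin, was higher by 0.35 ± 0.0625. Their limma adjusted p-values lay between 0.169 and 0.222, those of MYL6 and ADD3 included. In all, limma called 1 of 2695 events at the threshold, and 175 had an unadjusted p under 0.05. Of the 64 with an unadjusted p under 0.01, 53 were lower and 11 higher. With the replicate block 4 events passed: MARK3 (adjusted p = 0.0357), PPP3CB (0.0375), an exon of ARHGAP17 (0.68 ± 0.127 to 0.24 ± 0.184, adjusted p = 0.012), and an exon of the myotubularin-related protein SBF1 (0.65 ± 0.099 to 0.18 ± 0.0566, adjusted p = 0.018; SD, n = 2 for both). The quasi-binomial model of the reads called 2 events, and 63 with the block. MARK3 and MYL6 were among the 63 (adjusted p = 0.0294 and 0.0051 in that model). Losses without 1 library, here and in the other lines, come from fits with no replicate term and unequal shares of the replicate sets. The limma call of MARK3 was lost with no read minimum (adjusted p = 0.069), log2 odds (0.189), the read ratio (0.0602), the quasi-binomial model (0.0915) and only the libraries of the comparison (0.730). It was also lost without empty-vector control replicate 2 (0.0987), either empty-vector TIP60-siRNA library (0.135 and 0.114), either wild-type control library (0.0518 and 0.052), and any catalytically dead library (0.167, 0.168, 0.0702 and 0.0746), while without empty-vector control replicate 1 the number of events past the threshold was 7 and without empty-vector TIP60-siRNA replicate 2 it was 2.

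Among the gene lists in empty-vector cells, the epithelial-mesenchymal splicing programme had 3 of 27 genes with an event at an unadjusted p under 0.01, all lower (MARK3, SLC37A2 and CLSTN1; Fisher's exact adjusted p = 0.423). 1 gene passed over all events and 3 passed when adjusted over the list alone. The actin and adhesion list also had 3 of 27 (ADD3 higher, MYL6 and SYNE2 lower; adjusted p = 0.423), with 0 past the threshold over all events and 3 adjusted over the list alone. Splicing regulators had 2 of 18, HNRNPC and RBM4 (−0.19 ± 0.0475), both lower (adjusted p = 0.629), with 0 over all events and 1 adjusted over the list alone. The apoptosis list had 1 of 17, the caspase-8 regulator CFLAR (−0.075 ± 0.0181), with 0 over all events and 0 adjusted over the list alone, and its next member was CASP1 (−0.095 ± 0.0274). The remaining lists had 0 genes under 0.01, 0 past the limma threshold over all events and 0 adjusted over the list alone. At an unadjusted p under 0.05 they held 2 of 14 chromatin genes (SIRT6 0.07 ± 0.0274 and HDAC7 −0.265 ± 0.111), 2 of 17 cell cycle genes (CCND3 −0.095 ± 0.0292 and KIF23 −0.115 ± 0.0465), 1 of 4 RNA decay genes (CNOT4 0.275 ± 0.093), and 1 of 6 epithelial markers (TP63 0.18 ± 0.067). They held 0 of 3 NuA4 genes, 6 SR genes, 13 DNA damage genes, 6 interferon genes and 1 mesenchymal marker. In these lists the members of smallest p were BRD8 (−0.1 ± 0.0539) and RUVBL2 (0.005 ± 0.0236) of the TIP60 complex, RNPS1 (−0.155 ± 0.126) and SON (−0.03 ± 0.0268), CHEK2 (−0.07 ± 0.0522) and ERCC1 (0.045 ± 0.0353), PML (−0.195 ± 0.0859) and IRF3 (−0.025 ± 0.0155), EXOSC1 (−0.075 ± 0.0584), ESRP1 (−0.12 ± 0.0982), and FN1 (0.18 ± 0.196).

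The same siRNA in wild-type TIP60 cells asked what remained of the response where a resistant active copy was present. The exons with the clearest differences were again in MYL6 (0.78 ± 0.0283 to 0.315 ± 0.0212, SD, n = 2), ADD3 (0.18 ± 0.113 to 0.715 ± 0.106), MARK3 (0.285 ± 0.0354 to 0.065 ± 0.0636) and AKT2 (0.93 ± 0.0141 to 0.805 ± 0.00707), and none of them passed the limma correction (adjusted p = 0.188 for each). ABCB8, a mitochondrial transporter, had 0.67 in both control libraries and 0.95 ± 0.0283 with TIP60 siRNA (chromosome 7, 151033605 to 151033917, adjusted p = 0.188). Lower levels with non-overlapping libraries were also seen in ABI1, a regulator of actin assembly (−0.39 ± 0.0745), the receptor kinase MST1R (−0.41 ± 0.0878), the pyrophosphatase PPA2 (−0.19 ± 0.0402), ARHGAP8 (−0.175 ± 0.0323) and VRK3 (−0.16 ± 0.0264). Their limma adjusted p-values ran from 0.216 to 0.584. Limma called 0 of 2695 events in wild-type cells, with 116 at an unadjusted p under 0.05, and the quasi-binomial model also called 0 (171), and 24 with the block. With the replicate block 4 events passed, all lower: ARHGAP17 (−0.525, adjusted p = 0.00417), SBF1 (−0.465, 0.0192), HDAC7, a class II histone deacetylase (−0.515, 0.0209), and AKT2 (−0.125, 0.0418). Without either empty-vector control library limma called 2 events.

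In wild-type cells the actin and adhesion list had 3 of 27 genes under 0.01 (ADD3 higher, MYL6 and DST lower; Fisher's exact adjusted p = 0.177), with 0 past the threshold over all events and 3 adjusted over the list alone. The epithelial-mesenchymal list had 2 of 27, MARK3 and the plakin DST (−0.175 ± 0.0398), both lower (adjusted p = 0.600), with 0 over all events and 1 adjusted over the list alone. Chromatin factors had 1 of 14, HDAC7 (0.845 ± 0.0919 to 0.33 ± 0.0566), with 0 over all events and 1 adjusted over the list alone, and HDAC2 differed by 0.025 ± 0.0165. Splicing regulators had 1 of 18, HNRNPC (−0.06 ± 0.0161), with 0 over all events and 0 adjusted over the list alone, and RBM4 differed by −0.135 ± 0.0475. In the remaining lists 0 genes were under 0.01, 0 passed limma over all events and 0 adjusted over the list alone. At an unadjusted p under 0.05 they held 1 of 17 apoptosis genes and 1 of 17 cell cycle genes (CCND3 −0.08 ± 0.0296), and 0 genes in the other lists. Their other members of smallest p were CASP1 (−0.125 ± 0.0551), SKA2 (0.115 ± 0.0623), BRD8 (−0.13 ± 0.0736), RUVBL2 (0.01 ± 0.0236), TRA2A (−0.05 ± 0.0406), SRSF7 (0.03 ± 0.0292), UIMC1 (0.17 ± 0.115), BABAM1 (0.01 ± 0.0082), CNOT4 (0.125 ± 0.093), EXOSC1 (−0.08 ± 0.0663), IRF3 (−0.045 ± 0.0272), MAVS (−0.08 ± 0.0548), TP63 (−0.085 ± 0.067), ITGB4 (−0.02 ± 0.0249) and FN1 (−0.03 ± 0.196).

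In catalytically dead TIP60 cells, where the resistant copy was inactive, the MARK3 exon fell from 0.475 ± 0.00707 to 0.055 ± 0.0212 (SD, n = 2), a change of −0.42 (SE 0.0342, limma adjusted p = 0.0142). The HNRNPC exon did not pass, with 0.805 ± 0.00707 and 0.66 ± 0.0141 (limma adjusted p = 0.0572). MYL6 (0.795 ± 0.00707 to 0.25 ± 0.0707), AKT2 (0.94 to 0.815 ± 0.00707) and ADD3 (0.045 ± 0.00707 to 0.65 ± 0.0849) each had a limma adjusted p of 0.0705. Further exons with lower levels and adjusted p-values of 0.205 to 0.219 were in ABI1 (−0.46 ± 0.0745), the tetraspanin TSPAN4 (−0.25 ± 0.044), the p53-inducible oxidoreductase TP53I3 (−0.215 ± 0.0386), the guanylate kinase GUK1 (−0.17 ± 0.0292) and the microsomal glutathione transferase MGST1 (−0.035 ± 0.00594).

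Limma called 1 of 2695 events in catalytically dead cells, with 181 at an unadjusted p under 0.05. Of 63 events under 0.01, 59 were lower and 4 higher. With the replicate block 10 events passed, namely ARHGAP17 (−0.52, adjusted p = 0.00442), HNRNPC and SBF1 (−0.145 and −0.485, 0.0108 each), MARK3 (0.0118), MYL6, AKT2 and PPP3CB (−0.545, −0.125 and 0.335, 0.0303 each), the zinc finger protein MAZ (−0.17, 0.0438), and ABI1 and TP53I3 (0.047 each). The quasi-binomial model called 3 events, and 84 with the block. The limma call of MARK3 was lost on log2 odds (adjusted p = 0.152), with only the libraries of the comparison (0.459), without either control library of the line (0.222 and 0.251) and without either TIP60-siRNA library of the line (0.0806 and 0.153). The number of events past the threshold was 5 without either empty-vector control library, 8 without either empty-vector TIP60-siRNA library, 2 without either wild-type control library, and 0 without catalytically dead control replicate 1 or 2 or TIP60-siRNA replicate 2.

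Gene lists passed in catalytically dead cells alone among the 3 lines, although the difference between lines was not tested for lists. The epithelial-mesenchymal splicing programme had 5 of 27 genes with an event under 0.01 (18.5%, against 2.96% of other genes; Fisher's exact adjusted p = 0.0252), all with lower inclusion: MARK3, CLSTN1 (−0.125 ± 0.0263), SLC37A2, the integrin ITGA6 and MPZL1. 1 gene passed over all events and 4 adjusted over the list alone. The actin and adhesion list had 5 of 27 with the same p (ADD3 higher, MYL6, ITGA6, the nesprin SYNE2 and the tropomyosin TPM3 lower), with 0 over all events and 5 adjusted over the list alone, and ITGA6 counts in both lists. With the replicate block both adjusted p-values were 0.134. The number of lists that passed was 0 at an unadjusted p under 0.05 and 0 with at least 20 reads. It was 0 without any 1 of the catalytically dead libraries or the empty-vector TIP60-siRNA libraries, 1 without either empty-vector control library or wild-type control replicate 1, and 5 without wild-type control replicate 2.

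The other lists in catalytically dead cells did not pass. Splicing regulators had 1 of 18 genes under 0.01 (HNRNPC), with 0 over all events and 1 adjusted over the list alone, and RBM4 differed by −0.155 ± 0.0475. The rest had 0 genes under 0.01, 0 past limma's threshold over all events and 0 adjusted over the list alone. At an unadjusted p under 0.05 they held 4 of 17 apoptosis genes, the proapoptotic BID (−0.125 ± 0.0475) among them, 2 of 14 chromatin genes, namely SMARCA4, the catalytic subunit of a remodeller (0.04 ± 0.0118), and HDAC7 (−0.3 ± 0.111), and 1 of 17 cell cycle genes, the spindle protein PRC1 (−0.04 ± 0.0138). The other members of smallest p were CCND3 (−0.045 ± 0.0296), BRD8 (0.03 ± 0.0539), MORF4L2 (−0.07 ± 0.275), SRSF7 (−0.06 ± 0.0292), RNPS1 (−0.125 ± 0.126), ERCC1 (−0.09 ± 0.0659), TDP1 (−0.035 ± 0.0265), CNOT4 (0.07 ± 0.093), IRF3 (−0.02 ± 0.0155), PML (−0.11 ± 0.115), CDH1 (−0.03 ± 0.0193), LAMA3 (0.005 ± 0.00901) and FN1 (0.07 ± 0.196).

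**Figure D2:**
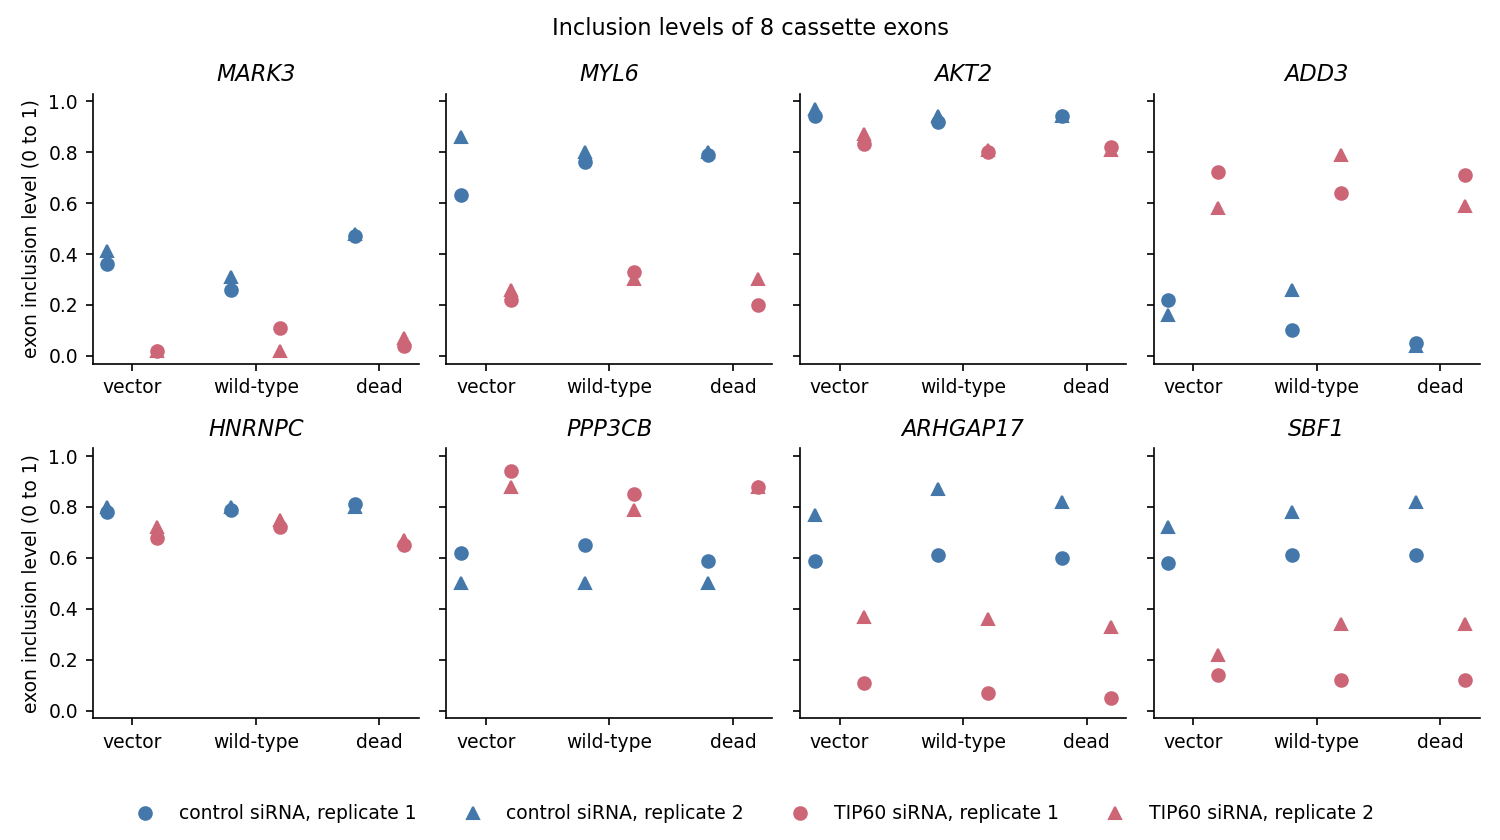
Inclusion level (0 to 1) of 8 cassette exons in each of the 12 libraries, by construct, with the siRNA as colour and the replicate number as marker. ADD3 and PPP3CB were higher with TIP60 siRNA and the other 6 exons lower, in each of the 3 lines.

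Exons separated by siRNA were mostly lower with TIP60 siRNA, and several were shared by the 3 lines. In empty-vector cells 24 exons lay at least 0.1 higher and 70 at least 0.1 lower in both TIP60-siRNA libraries, against 3 and 5 for the split that mixes siRNA and replicate number. The counts were 9 and 59 in wild-type cells (crossed split 4 and 2) and 19 and 92 in catalytically dead cells (crossed split 7 and 6). The split by replicate number separated more exons, 401, 372 and 400 in the 3 lines. Separated in all 3 lines were 2 higher exons, ADD3 and PPP3CB, and 14 lower ones, in ABI1, ANKRD13D, ARHGAP17, JOSD2, MARK3, MON1A, MPRIP, MTA1, MYL6, OS9, POMT1, SBF1, SYNE2 and TRERF1. The crossed split separated 0 exons in all 3 lines, and the split by replicate number 122 one way and 90 the other. MPRIP binds myosin phosphatase and MTA1 belongs to the NuRD deacetylase complex. Without 1 library the separated counts were 234 to 325 in empty-vector cells, 209 to 256 in wild-type cells and 257 to 350 in catalytically dead cells, where 3 libraries had to be apart in place of 4, a count added after values had been seen.

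**Figure D3:**
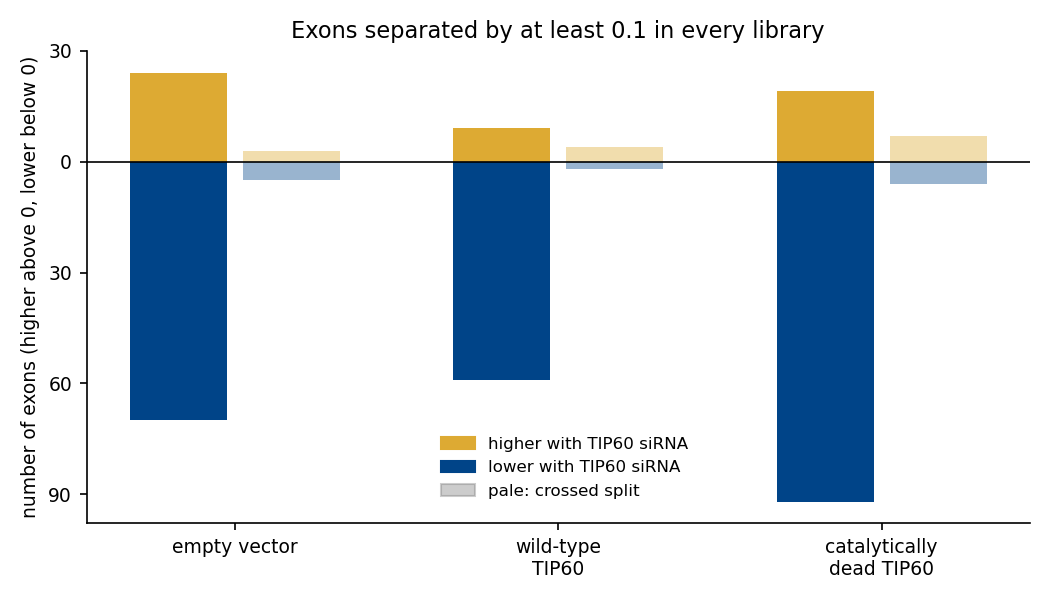
Number of exons whose TIP60-siRNA libraries all lay at least 0.1 above (upward bars) or below (downward bars) the control libraries of the line, with the crossed split of the same 4 libraries in pale bars. Lower exons numbered 70, 59 and 92 in empty-vector, wild-type and catalytically dead cells, against 5, 2 and 6 for the crossed split.

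The next comparison asked whether exons that responded in empty-vector cells responded less where wild-type TIP60 was present. On the 64 exons picked in empty-vector cells at an unadjusted p under 0.01, which include those of MARK3, MYL6, ADD3, AKT2 and PPP3CB, the mean shift in the same direction was 0.113 in wild-type cells (limma fry, adjusted p = 7.0e-05, same sign for 53 exons) and 0.159 in catalytically dead cells (adjusted p = 4.7e-06, same sign for 59). It was 0.207 in empty-vector cells themselves, where the picking of the exons inflates it. Within the first set the shift was 0.116 ± 0.0179 in wild-type cells and 0.155 ± 0.0197 in catalytically dead cells (SE over events, which are not independent replicates), and within the second set 0.109 ± 0.0184 and 0.163 ± 0.0182. The shift was larger in catalytically dead cells by 0.0461 (limma fry, adjusted p = 0.0047). With the replicate block the difference was 0.0377 over 110 exons picked in that fit (limma fry, adjusted p = 0.00587). Exons were picked with a spread from all 12 libraries, which fry used again, so that its p-values can be too small. Picked and tested on separate libraries, the shifts were 0.169 over 31 exons in wild-type and 0.218 over 23 in catalytically dead cells (limma fry, adjusted p = 0.00436 and 0.000572). With 11 exons picked at an unadjusted p under 0.001 the shifts were 0.170 and 0.269 and their difference 0.0982 (limma fry, adjusted p = 0.0199). With 175 picked under 0.05 they were 0.0896 and 0.122 with a difference of 0.0325 (adjusted p = 0.00528). Leaving out 1 library, with no replicate term, also compared unequal shares of the replicate sets in the line that lost it. In fits on fewer libraries the exons were picked again, so that both the libraries and the exons changed. There the difference did not pass without empty-vector control replicate 1 (0.0395 over 48 exons, limma fry adjusted p = 0.122), without empty-vector TIP60-siRNA replicate 2 (0.0279 over 78 exons, adjusted p = 0.206), or with only the libraries of the comparison (0.0667 over 23 exons, adjusted p = 0.133). Without empty-vector TIP60-siRNA replicate 2 the shifts themselves were 0.0744 in wild-type and 0.102 in catalytically dead cells (limma fry, adjusted p = 0.00341 and 0.00159).

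**Figure D4:**
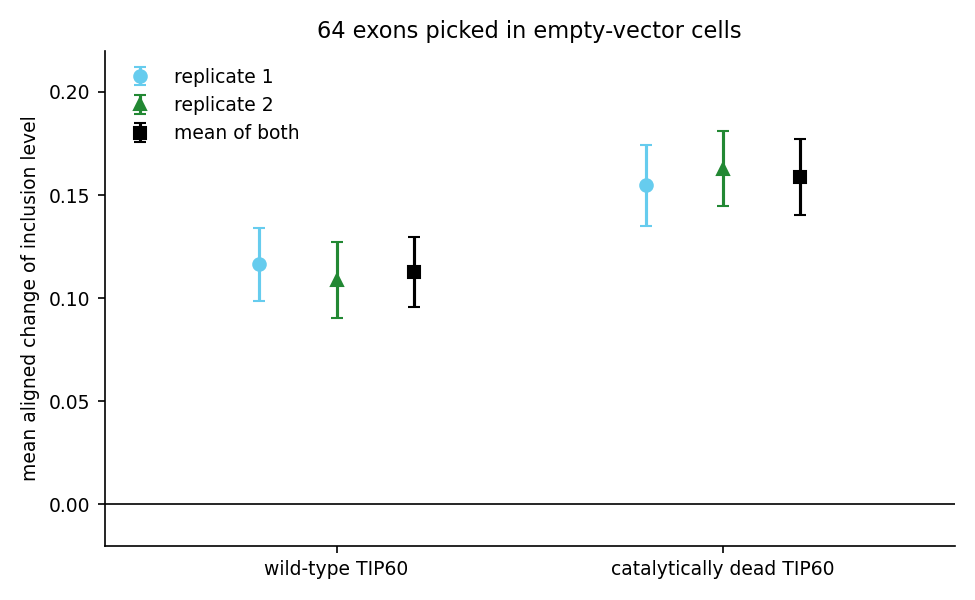
Mean change of inclusion level with TIP60 siRNA, aligned to the direction in empty-vector cells, of the 64 exons picked there, in the lines with wild-type and catalytically dead TIP60. Points are the replicate sets and their mean, bars are SE over events, and the mean was 0.113 in wild-type and 0.159 in catalytically dead cells.

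For single exons no difference between siRNA responses passed. Between empty-vector and wild-type cells, the SLC37A2 exon (chromosome 11, 125086204 to 125086260) had the smallest p: its level went from 0.63 to 0.16 in empty-vector cells and from 0.615 to 0.64 in wild-type cells, a difference of −0.495 (SE 0.105, limma unadjusted p = 0.00217, adjusted p = 1.00). The next were VRK3 (0.165 ± 0.0373), ARHGAP8 (0.2 ± 0.0456), AGPAT4 (−0.195 ± 0.0449) and AMIGO2 (−0.225 ± 0.0518). Between catalytically dead and wild-type cells they were ARHGAP8 (0.205 ± 0.0456), MARK3 (−0.2 ± 0.0483), VRK3 (0.15 ± 0.0373), the deubiquitinase USP48 (−0.12 ± 0.032) and HNRNPC (−0.085 ± 0.0228). Between catalytically dead and empty-vector cells they were AMIGO2 (0.195 ± 0.0518), PTP4A2 (−0.115 ± 0.0314), BTN2A1 (0.27 ± 0.0752), TMUB2 (0.215 ± 0.0637) and TSPAN3 (−0.02 ± 0.00627). Limma called 0 events in each, with 44, 32 and 36 at an unadjusted p under 0.05, and called 0 with the replicate block (96, 79 and 78), as did the quasi-binomial model without the block (69, 52 and 54) and with it (196, 161 and 173).

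The constructs were compared under control siRNA to ask whether they altered exon choice by themselves. Wild-type against empty-vector cells gave smallest p-values for ARHGAP8 (0.93 against 0.78, SE of the difference 0.0323), SDR39U1 (0.895 against 0.73), CPPED1 (0.925 against 0.985), PIGT (0.975 against 0.935) and the calsyntenin CLSTN1 (0.04 against 0.135). Catalytically dead against empty-vector cells gave VRK3 (0.86 against 0.75, SE of the difference 0.0264), the kinase MAP3K7 (0.96 against 0.855), TMEM9B (0.795 against 0.65), TMUB2 (0.655 against 0.83) and PTP4A2 (0.93 against 0.85). Limma called 0 events in each comparison (adjusted p = 1.00 for these exons), with 42 and 21 at an unadjusted p under 0.05, 0 with the replicate block (121 and 85) and 0 with the quasi-binomial model (70 and 49). The quasi-binomial model with the block called 2 overlapping events of the non-coding gene LRRC75A-AS1 in wild-type against empty-vector cells, both higher (0.09 and 0.05, adjusted p = 0.00686 and 0.0372 in that model, named after their values were seen), and 0 in catalytically dead against empty-vector cells (201). The log2 read ratio with the block called 0 in each comparison.

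The resistant copies were compared under TIP60 siRNA, where the endogenous gene was depleted. SLC37A2 had an inclusion level of 0.64 with the wild-type copy and 0.14 with the catalytically dead copy, a difference of 0.5 (SE 0.0742, limma adjusted p = 0.538). VRK3 had 0.685 and 0.85 (−0.165 ± 0.0264, adjusted p = 0.538), ARHGAP8 0.755 and 0.905 (−0.15 ± 0.0323), and HNRNPC 0.735 and 0.66 (0.075 ± 0.0161). An exon of RNASEK-C17orf49, a read-through gene whose reads cannot be assigned to 1 of its genes with certainty, had 0.86 and 0.75 (0.11 ± 0.0234). Limma called 0 events, with 67 at an unadjusted p under 0.05, and 0 with the replicate block (141) or the quasi-binomial model (96). The quasi-binomial model with the block called 10, a setting added after values had been seen, and 5 of these were higher with the wild-type copy, among them 2 of LRRC75A-AS1 (0.155 and 0.175), SLC37A2 (adjusted p = 0.0226 in that model) and ITGA6 (0.225, adjusted p = 0.0226). ZDHHC7 was lower by 0.24 (adjusted p = 0.0292 in that model). The log2 read ratio with the block, also added after values had been seen, called 0 events in this comparison. With weights from the intervals limma called SLC37A2 (adjusted p = 0.0132). Without catalytically dead TIP60-siRNA replicate 1 it called 1.

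Event reads of the marker lists were read for signs of other cells or a response to transfection. With TIP60 siRNA the median log2 change of 9 interferon genes was −0.31 in empty-vector, 0.02 in wild-type and 0.11 in catalytically dead cells. For 6 epithelial markers it was 0.05, 0.06 and −0.01, and for the mesenchymal markers with an event, FN1 and DCN, 1.18, 0.92 and 1.07, against −0.09, −0.05 and −0.14 for all 4992 events. Limma called 0 genes of these lists in any line, with or without the replicate block, and 0 of 4992 events of any kind in the group-only fit, with 238, 94 and 233 at an unadjusted p under 0.05.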

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

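The tests on exons picked in catalytically dead cells, those on event reads, and the tests of constructs missing, full restoration, partial restoration and unequal constructs were chosen after the results they bear on had been seen. Responses that differed between cell lines are given first. On the 64 exons picked in empty-vector cells the siRNA shift was larger in catalytically dead than in wild-type cells by 0.0461 (limma fry, adjusted p = 0.0047). On 63 exons picked in catalytically dead cells it was larger in empty-vector than in wild-type cells by 0.0408 (limma fry, adjusted p = 0.0027; 0.0215 and adjusted p = 0.0423 with the replicate block). Fits without 1 library, here and for event reads below, had no replicate term. The line that lost the library compared unequal shares of the 2 replicate sets. The difference on exons picked in catalytically dead cells turned to −0.0140 without empty-vector control replicate 2. It did not pass without wild-type control replicate 2 (0.0437, limma adjusted p = 0.0908), catalytically dead control replicate 1 (0.0404, 0.0912) or either catalytically dead TIP60-siRNA library (0.0303, 0.120 and 0.0319, 0.138). On 36 exons picked in wild-type cells, catalytically dead and empty-vector cells differed by 0.0103 (limma fry, adjusted p = 0.469).

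Event reads gave 2 differences of the same kind, which were again both taken against the same wild-type libraries. The 62 events with an unadjusted p under 0.01 in empty-vector cells shifted more in catalytically dead than in wild-type cells by 0.41 on the log2 scale (1.45 against 1.05; limma fry, adjusted p = 0.0132). The difference did not pass without empty-vector control replicate 1 (0.29, limma adjusted p = 0.128), empty-vector TIP60-siRNA replicate 2 (0.45, 0.117), catalytically dead control replicate 1 (0.35, 0.0504) or catalytically dead TIP60-siRNA replicate 2 (0.26, 0.0847), and it was 0.62 without empty-vector control replicate 2. The 64 events picked in catalytically dead cells shifted more in empty-vector than in wild-type cells by 0.61 (1.52 against 0.91; limma fry, adjusted p = 0.0042), which did not pass without catalytically dead control replicate 2 (0.54, limma adjusted p = 0.0947) or TIP60-siRNA replicate 1 (0.54, 0.087). With scaling by the median of ratios the differences were 0.48 and 0.59.

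Reads at the KAT5 event that fitted neither annotated form entered no test of inclusion levels or event reads. Their ratios were taken between the constructs and between the siRNAs. The ratios of TIP60-siRNA to control RPM in the first and second set were 0.288 and 0.393 in empty-vector cells, 0.690 and 0.829 in wild-type cells, and 0.966 and 0.733 in catalytically dead cells. The reads fitting neither form numbered at least 17692 in the wild-type libraries and at least 8983 in the catalytically dead libraries, against at most 177 in the empty-vector libraries.

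The pattern weighed here is that exons responding in empty-vector cells also shifted in cells with wild-type TIP60. A difference in level between the replicate sets cancels in each siRNA effect, because each set holds all 6 groups, so that the within-set shifts do not test it. The lower of these shifts, 0.109, was over 2 standard errors above 0 (over events, which are not independent replicates), so that the pattern was present in both sets. Wild-type libraries without the construct are argued against by KAT5 exclusion reads at least 9.17 times the highest empty-vector library. Full restoration by the wild-type copy stays open: the shift of 0.113 is the pattern itself and excludes nothing. Effects of the siRNA on transcripts other than KAT5, which were not tested, would also give it. The KAT5 form with the exon still fell with TIP60 siRNA in wild-type cells, from 11.6 to 2.74 RPM in the first set and from 5.31 to 1.34 in the second. Under control siRNA that form stood at 11.6 and 5.31 RPM in wild-type cells, against 17.2 and 5.84 in empty-vector cells. These values argue against the construct as a source of that form, although they rest on few reads. Whether the form without the exon can replace it was not tested. Partial restoration by the active copy stays open as a hypothesis: the smaller of the 2 differences against the wild-type line was 0.0408 and both passed in the full data. Both differences were taken against the same 4 wild-type libraries, so that they are not independent of each other. The rule was made stricter once fits without 1 library, on exons picked again, were seen to end or turn them. Those fits had no replicate term, so that they do not settle whether the differences hold. With the replicate block, on exons picked again, the differences were 0.0377 over 110 exons and 0.0215 over 109 (limma fry, adjusted p = 0.00587 and 0.0423). Picking and test shared their libraries there too. Unequal constructs also stay open, since the KAT5 reads that came with the construct were fewer in catalytically dead cells, at 0.535 times the wild-type value or lower for reads without the exon and 0.597 and 0.441 times for reads fitting neither form, so that lower amount and lost activity cannot be told apart.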

How the results depend on the processing

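The fits with read-based models and the replicate block together, primary chromosomes alone, separated exons and gene lists under left-out libraries, and every setting of the average siRNA effect were chosen after the results had been seen. Limits come first from the 2 libraries per group and from the pairing by replicate number. Taking the replicate block up gave 4, 4 and 10 exons past the threshold in empty-vector, wild-type and catalytically dead cells, against 1, 0 and 1 without it. The block with the quasi-binomial model gave 63, 24 and 84, and with the log2 read ratio 54, 18 and 76. The quasi-binomial model alone gave 2 in empty-vector and 3 in catalytically dead cells, the read ratio alone 2 and 3, log2 odds 0 and 0, only the libraries of the comparison 0 and 0, and interval weights 9 and 18. No read minimum gave 0 in empty-vector cells and at least 20 reads gave 2 in catalytically dead cells. Without 1 library the numbers were 0 to 7, 0 to 2 and 0 to 8. For wild-type against empty-vector cells under control siRNA the quasi-binomial model with the block gave 2, and for the resistant copies under TIP60 siRNA it gave 10, interval weights 1 (SLC37A2), and left-out libraries 0 to 1. The replicate block left the siRNA differences of level unchanged and altered only their estimated spread. In empty-vector cells the SE went from 0.165 to 0.0291 for ARHGAP17 and from 0.0342 to 0.0348 for MARK3. The cause of the other differences between settings was not tested.

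The set shift, on exons picked again in each fit, ranged without 1 library from 0.0744 to 0.131 in wild-type cells, from 0.102 to 0.172 in catalytically dead cells, and from 0.0279 to 0.0619 for their difference, which was 0.0667 and did not pass with only the libraries of the comparison. With exons picked at p under 0.001 and 0.05 it was 0.170 and 0.0896 in wild-type cells, 0.269 and 0.122 in catalytically dead cells, and 0.0982 and 0.0325 for their difference; it was not run with the quasi-binomial model. With the replicate block the set shift was 0.108 in wild-type and 0.146 in catalytically dead cells over 110 exons, with a difference of 0.0377. That difference was 0.0677 on log2 odds, 0.0327 on the read ratio and 0.0461 with at least 20 reads. These differences passed (limma fry, adjusted p = 0.00587, 0.00215, 0.012 and 0.0057 in this order). Separated exons numbered 21, 14 and 37 at a gap of 0.2, 223, 160 and 219 at 0.05, 23, 17 and 33 where deposited intervals did not overlap, and 223, 192 and 244 with no read minimum, in the order empty vector, wild type and catalytically dead. With at least 20 reads they were 40 in wild-type and 72 in catalytically dead cells, and without 1 library 234 to 325, 209 to 256 and 257 to 350. The number of gene lists past the threshold, 2, was 0 at an unadjusted p under 0.05, 0 with the replicate block, 0 with at least 20 reads, and 0 to 5 without 1 library. Exons changed on average numbered 182, and 82 with no replicate block, 324 on log2 odds, 389 on the read ratio, 118 at a change of at least 0.1, and 94 to 160 without 1 library.

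Total KAT5 event reads, fitted without the pairing, reversed in wild-type cells to 1.93 without control replicate 1 and 1.87 without TIP60-siRNA replicate 2 (range −2.71 to 1.93), and in catalytically dead cells to 1.97 without control replicate 1 and 2.16 without TIP60-siRNA replicate 2 (range −2.88 to 2.16); the range in empty-vector cells was −2.93 to −1.02. Among 128 named exon results, 3016 of 3050 alternatives kept the direction, 133 brought a result past the threshold and 20 lost a call. The 34 reversals were all in exons that did not pass in the group-only limma fit. In empty-vector cells RUVBL2 turned to −0.077 on log2 odds, −0.0866 in the quasi-binomial model (−0.0318 with the block), and −0.025 and −0.01 without control replicate 2 or TIP60-siRNA replicate 1 (range without 1 library −0.025 to 0.035). ERCC1 turned to −0.20 on the read ratio (−0.14 with the block), −0.0286 in the quasi-binomial model (−0.134 with the block) and −0.005 without control replicate 2 (−0.005 to 0.095). In wild-type cells TP63 turned to 0.49 on the read ratio without or with the block, 0.609 in the quasi-binomial model (0.506 with the block) and 0.005 without TIP60-siRNA replicate 1 (−0.175 to 0.005), EXOSC1 to 0.025 without TIP60-siRNA replicate 2 (−0.185 to 0.025), ITGB4 to 0.005 without control replicate 2 (−0.045 to 0.005), and FN1 to 0.11 and 0.19 without control replicate 2 or TIP60-siRNA replicate 1 (−0.25 to 0.19). In catalytically dead cells BRD8 turned to −0.048 on the read ratio (−0.068 with the block), −0.0596 in the quasi-binomial model (−0.0636 with the block), and −0.03 and −0.01 without control or TIP60-siRNA replicate 2 (−0.03 to 0.09), and CDH1 to 0.35 on the read ratio (0.36 with the block) and 0.277 in the quasi-binomial model without or with the block. There MORF4L2 turned to 0.135 and 0.145 (−0.285 to 0.145) and FN1 to −0.165 and −0.015 (−0.165 to 0.305) without control replicate 1 or TIP60-siRNA replicate 2, and LAMA3 to −0.005 without TIP60-siRNA replicate 1 (−0.005 to 0.015).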

Other observations

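The average siRNA effect, its other splits, the genes named from event reads and the gene lists on the average were chosen after the data had been seen. Taken over the 3 lines, with terms for construct and replicate number, 182 of 2695 exons changed with TIP60 siRNA (limma), 35 higher and 147 lower. Inclusion rose in ADD3 (0.138 ± 0.0904 to 0.672 ± 0.0823, SD, n = 6, limma adjusted p = 0.00116), PPP3CB (0.56 ± 0.0684 to 0.87 ± 0.049, adjusted p = 0.000488), the splicing regulator HNRNPA2B1 (0.123 ± 0.0472 to 0.335 ± 0.119, adjusted p = 0.0038) and the spectrin SPTAN1 (0.733 ± 0.0857 to 0.927 ± 0.0137, adjusted p = 0.022). It fell in MYL6 (0.773 ± 0.0774 to 0.268 ± 0.0508, adjusted p = 0.000131), ARHGAP17 (0.71 ± 0.125 to 0.215 ± 0.153) and SBF1 (0.687 ± 0.101 to 0.213 ± 0.105, adjusted p = 8.2e-06 for both), ABI1 (−0.41), the kinase PAK4 (−0.373), MPRIP (−0.362), HDAC7 (−0.36), MTA1 (−0.345) and MARK3 (−0.335), each in 6 of 6 same-number pairs. Splicing regulators had 6 of 18 genes changed (33.3% against 8.19% of other genes, Fisher's exact adjusted p = 0.024): HNRNPA2B1 and HNRNPD higher, HNRNPC (−0.0983), RBM4 (−0.16), SF1 (−0.0917) and HNRNPA1 lower, the last uncertain because near-identical pseudogenes share its reads. The epithelial-mesenchymal programme had 7 of 27 (adjusted p = 0.024), 3 higher and 4 lower, among them SEC31A (0.185) and ATP5F1C higher and NUMB, an inhibitor of Notch signalling (−0.153), ITGA6 (−0.217), MPZL1 and MARK3 lower. The actin and adhesion list had 7 of 27 (adjusted p = 0.024), 3 higher and 4 lower, among them ADD3 and SPTAN1 higher and MYL6, SYNE2 (−0.238), ITGA6 and TPM3 lower. Adjusted over the list alone 7, 14 and 9 genes passed in these 3 lists. Other lists did not pass: apoptosis 3 of 17 (among them BID −0.11 and PDCD10 0.0683; 3 adjusted over the list alone), chromatin 2 of 14 (HDAC7, SMARCA4; 5), SR proteins 1 of 6 (RNPS1; 1), cell cycle 1 of 17 (CCND3; 1), and 0 in the rest with 0 adjusted over the list alone. The number of changed exons was 95 without empty-vector control replicate 2, 119 without wild-type control replicate 1, 94 and 101 without either catalytically dead control library, 106 and 113 without either catalytically dead TIP60-siRNA library, and 82 without the replicate term.

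Event reads called no event in the group-only limma fit (238, 94 and 233 at an unadjusted p under 0.05) but 154, 1 and 142 events with the replicate block in empty-vector, wild-type and catalytically dead cells. CCNG1, a cyclin induced by p53, fell by 2.14, 2.02 and 2.16 on the log2 scale (limma adjusted p = 0.00238, 0.00392 and 0.00214 with the block), from 1518 ± 669 to 337.2 ± 111.3 RPM in empty-vector cells (SD, n = 2). MMP28, a secreted metalloprotease, rose by 3.38 and 3.40 in empty-vector and catalytically dead cells (limma adjusted p = 0.00399 and 0.00302) and differed by 1.69 in wild-type cells (adjusted p = 0.185), although the differences between lines did not pass (1.70 and 1.71, limma adjusted p = 1.00 for both). With the block, reads of the transporter ABCC5 rose by 1.99 and 2.01 and of SLC37A2 by 1.54 and 1.92 in the same 2 lines, and those of JADE2 fell by 1.64 and fell by 1.77. Reads of the protease inhibitor SPINT2 fell by 1.30 and fell by 1.64, and those of the integrin ITGB1 fell by 0.77 and fell by 0.81. In wild-type cells the reads of these genes moved the same way but did not pass. The log2 changes there were 1.42 for ABCC5, 0.65 for SLC37A2, −0.96 for JADE2, −0.84 for SPINT2 and −0.75 for ITGB1. The cell cycle inhibitor CDKN1A rose by 1.28 in empty-vector cells (limma adjusted p = 0.0211) and differed by −0.01 and 0.71 in wild-type and catalytically dead cells. With the block no single event differed between lines in limma (0 events, with 145, 167 and 51 at an unadjusted p under 0.05), so that the unequal counts show no difference for any 1 gene. As sets, events picked in empty-vector or catalytically dead cells did shift more in the other of these lines than in wild-type cells with the block (by 0.42 over 388 events and 0.44 over 407, limma fry adjusted p = 0.0163 and 0.0082), and no biological explanation of this was tested. These 2 differences share the wild-type libraries.

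The large number of lower against higher exons was weighed against 3 technical explanations, each with a test written before its result was seen. Of 195 separated exons in any line, 151 fell (77.4%, exact interval 70.9 to 83.1). The exact intervals here take exons as independent, which exons measured in the same libraries are not, so that they can be too narrow. Posterior means pulled to the middle by shallow libraries are argued against by exons with at least 100 reads in every library of the line, of which 83.3% (20 of 24, exact interval 62.6 to 95.3) fell. GC content and length of the exon as the whole cause are argued against by the lower of the shares on either side of the median, 70.1% for GC (54 of 77, 58.6 to 80.0) and 69.0% for length (60 of 87, 58.1 to 78.5), both above 50 in their exact intervals. A bound of 50% takes rises and falls as equally possible, and the room left to rise was not weighed. For the average siRNA effect, the median control level was 0.872 in 2355 exons not called, 0.847 in 140 called lower and 0.562 in 30 called higher. Loss of TIP60 and other actions of the siRNA both stay open and untested here. An siRNA of another sequence would tell them apart.

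The difference between libraries numbered 1 and 2 was weighed against 2 technical explanations, with tests written before their results were seen, except that the correlations of read shares were chosen, and the bound for depth was taken as 5 in place of 10, afterwards. Read pairs may have fitted short events less often in the second set: across events, the log2 ratio of the share of reads fitting an isoform rose with the length of the flanking exons (Spearman rho = 0.593), from a median of 13.3% against 36.2% in the 674 events with the shortest flanks to 72.4% against 82.1% in the 674 with the longest. Lower depth as the whole cause is argued against by the 583 exons with at least 100 reads in every library, of which 10.6% differed by over 0.1 between the sets (62 exons, exact interval 8.25 to 13.4) where depth alone was to give under 5%, and in which deviations of read shares correlated between groups at Pearson r 0.820 to 0.906 in libraries of the same number. The exact interval takes exons as independent, which they are not. Each set held all 6 groups, and the labels do not say how the sets differ.

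Other splits of the 12 libraries were drawn for the average siRNA effect. Of 100 splits, the real one included, 1 gave as many as 182 exons, namely the real one, and the highest other gave 1. Among the 32 that part all 6 same-number pairs the highest other gave 0. In the other splits the siRNA effect stays in the residual spread, which by itself lowers their counts. They therefore do not show how many exons chance would give, although the real split gave the most of those drawn.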
